A study of Mus musculus with 6 samples.

How the data were processed

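Poly-A RNA was sequenced from CD45-negative cells of subcutaneous MC38 tumours, a mouse colon cancer line grown in wild-type C57BL/6 mice, with 3 libraries labelled wild type and 3 labelled Npm1 knockout. CD45 is the surface protein shared by leukocytes, and per the labels' protocols it was used with microbeads to take leukocytes out of the tumour suspension. The labels do not say whether replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

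The deposited values are FPKM, fragment numbers scaled to gene length and library size, with 1 column per library and no pooling of replicates. The submitters' processing notes list CASAVA 1.8, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 with the mouse build GRCm38 (mm10), and give no role for any of them. The authors' filters, strand setting and treatment of fragments that match several genes are not given in the sources used here. Near-identical copies can therefore share fragments, and a gene cannot be told apart from an overlapping antisense partner.

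FPKM multiplied by the gene length was a whole multiple of 1 step per library for 100% of values, within a tolerance of 0.001 of a fragment. The recovered totals ran from 16917778 to 18662688 fragments per library, and the total implied by the step was 0.96 to 1.04 times the recovered one. Of 54532 genes, 99.9% had their identifier in the GENCODE vM21 annotation of GRCm38, and 98.3% had the same coordinates there. Where a symbol stood on several rows, it was kept for the row with the highest mean FPKM.

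Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model on group, moderated variance with a mean trend, two-sided), over the 11287 genes with a mean of at least 1 FPKM over the 6 libraries. Adjusted p-values are Benjamini-Hochberg values, and a gene was said to rise or fall at an adjusted p under 0.05. Fold changes are knockout minus wild type on the log2(FPKM + 1) scale, which understates the change of low genes. Errors of levels are SDs over 3 libraries and errors of fold changes are limma's standard errors. Of 30 gene lists, the 19 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation was run beside it, as was fry, which tests whether a list's genes move one way on balance and makes no comparison with other genes.

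The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names Npm1, the 12 largest rises and 12 largest falls among protein-coding genes with groups that do not overlap, up to 4 members of each list with the smallest p, and a fixed set of antigen presentation genes. Some genes that the rule names are not reported here. Members outside the rule are named in places to say which genes make up a count, and those were chosen after their values were seen. The alternatives fixed in advance were another pseudocount (0.1), other filters, other scalings, other variance models, array weights, a replicate block and leaving out each library in turn.

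A correction for transcript length and GC content was added after a trend with both had been seen. In each library a smooth surface over GC content and log2 transcript length (mgcv 1.9.3) was subtracted from the log values, for the 11269 tested genes with both properties. Both were taken from each gene's longest annotated transcript. That transcript need not be the one expressed, so the corrected value of a single gene can be off. limma-voom on the recovered fragments and the correction combined with the replicate block or with each library left out were also added after seeing the data. The main results remained the uncorrected ones.

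The procedure was tested on simulated data for the knockout against wild-type comparison, with 200 genes changed among 11270 tested. It recovered 25.8% of genes changed 1.5-fold, 90.8% of those changed 2-fold and 100% of those changed 4-fold, and made 25 false calls, above the nominal rate. A length and GC trend was then added to the simulated knockout comparison over 11264 genes. There the uncorrected test made 209 false calls and the corrected test 69, beside at most 200 true ones. A pass with the trend removed can thus be false. Unlike in the data, the added trend ran along a single combined axis of length and GC and spared knockout replicate 3.

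Explanations were set against the data with tests whose criteria were written down. Carry-over of leukocytes was tested in 2 ways: first by the fold changes of leukocyte markers, and then, once that outcome was known, by the level of pan-leukocyte markers. Both are reported. The criterion for excluding a changed share of fibroblasts was made stricter after its outcome was seen, since the first version rested on 1 gene.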

Results

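Gene expression was measured by poly-A RNA sequencing in CD45-negative cells isolated from MC38 tumours, with 3 libraries labelled wild type and 3 labelled Npm1 knockout. Npm1 encodes nucleophosmin, a nucleolar chaperone with a part in ribosome assembly. The wild-type libraries held 18255574, 17247121 and 16917778 fragments and the knockout libraries 18662688, 17333843 and 18114322, so depth differed little between the groups. The only comparison in the design is knockout against wild type, and the series title places it in the study of antigen presentation by tumour cells.

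Npm1 itself (ENSMUSG00000057113, chromosome 11, 33152287 to 33163206, minus strand, GRCm38) was measured at 234, 169 and 195 FPKM in the wild-type libraries and at 191, 159 and 128 FPKM in the libraries labelled Npm1 knockout. The means were 200 ± 32.7 FPKM and 159 ± 31.3 FPKM (SD, n = 3 each), a log2 difference of -0.33 (SE 0.197, 95% interval -0.77 to 0.11, limma adjusted p = 0.268). An exact two-sided permutation test of the 6 values gave p = 0.2, where the smallest p possible with 3 against 3 is 0.1. The groups overlapped, so the Npm1 transcript level does not check the labels. A frameshift knockout need not lower the transcript, and the values hold no sequence. With the length and GC trend removed, the Npm1 difference was -0.77 (limma adjusted p = 0.0423), and limma adjusted p ran from 0.0189 to 0.146 when a library was then left out.

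**Figure D1:**
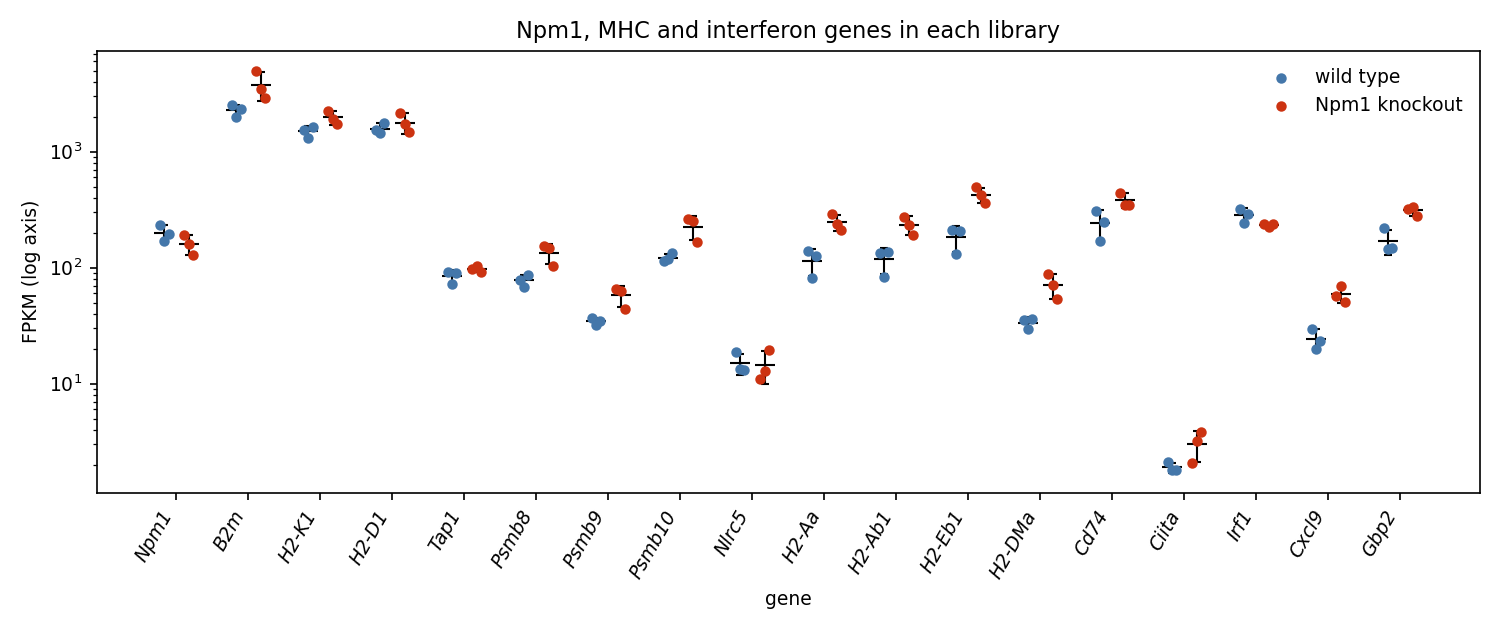
FPKM on a log axis for Npm1 and for MHC and interferon genes in each of the 6 libraries; points are libraries, horizontal marks are group means and bars are SDs (n = 3). H2-Eb1 lay at 183 ± 45.2 FPKM in wild type and at 427 ± 63.8 FPKM in the knockout, while the groups overlapped for Npm1.

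The libraries labelled Npm1 knockout held more MHC class II and interferon gamma response transcripts than the wild-type libraries, and less of the NF-kB target list, by camera at its preset correlation. None of these lists passed with an estimated correlation (adjusted p = 0.684, 0.725 and 0.695) or with fry. H2-Eb1, a class II chain, rose by a log2 change of 1.24 (SE 0.222, n = 3 each), and Csf2, the cytokine GM-CSF, fell by 2.18 (SE 0.19). Dpt, the matrix protein dermatopontin, rose from 23.1 ± 4.37 to 110.5 ± 30.7 FPKM. Pdgfb, a platelet-derived growth factor chain, fell from 43.9 ± 21.2 to 7.58 ± 0.703 FPKM.

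Of 11287 genes tested, 1604 changed, of which 667 were higher and 937 lower in the knockout. At least 2-fold changes numbered 79 upward and 152 downward. The groups did not overlap for 4016 genes (35.6%). The average share over all splits of the libraries is 10%, but genes move together, so a single split can lie far from it. The count depended on single libraries: 7 genes passed without wild-type replicate 3, 83 without knockout replicate 1, 200 without knockout replicate 2, 923 without wild-type replicate 2 and 2804 without knockout replicate 3. It was 290 with the length and GC trend removed, 5454 with array weights, and 0 in limma with no filter on low values, where 4543 of 24310 genes had an unadjusted p under 0.05. Rescaling to TPM gave 961 genes, 26.1% of them higher against 41.6% as deposited, and moved the median of all genes by -0.10.

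Fold change followed transcript length and GC content. Over 9824 protein-coding genes split into 5 equal bins, the median log2 change ran from 0.28 in the bin of shortest transcripts to -0.28 in the longest, and from 0.23 in the bin of lowest GC content to -0.19 in the highest. Genes that rose had a median transcript length of 2234 bases and those that fell 4842 bases. Spearman's rho of a library's deviations with length, taken across genes, which are not independent replicates, was 0.618, 0.214 and 0.138 in wild type and -0.614, -0.591 and 0.345 in the knockout, so knockout replicate 3 lay on the wild-type side for length. With GC content rho was -0.154, 0.455 and 0.606 in wild type and -0.218, -0.155 and -0.557 in the knockout, so there wild-type replicate 1 lay with the knockout and knockout replicate 3 was lowest. On the first principal component (54.7% of variance) knockout replicate 3 stood at 6.2, between wild type (-26.2 to -18.9) and the other knockout libraries (33.4 and 27.2). Lists called by camera are given below with the trend in place and removed.

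**Figure D2:**
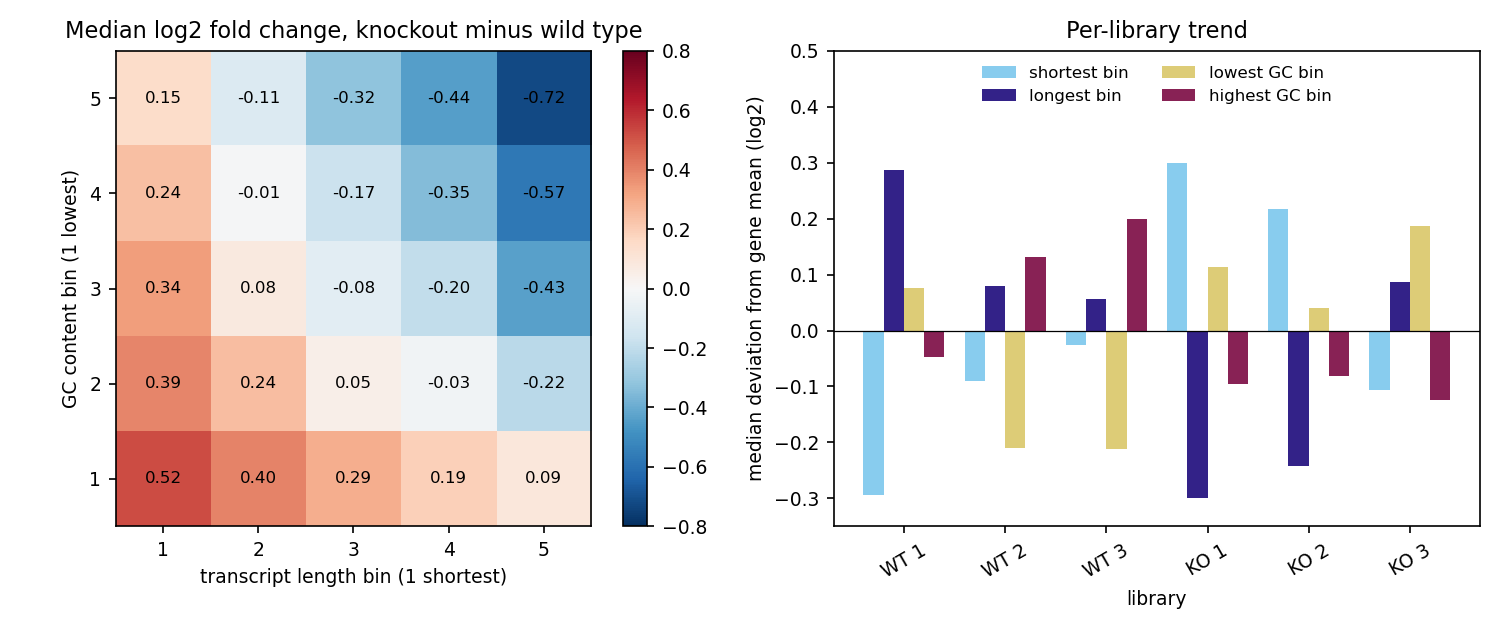
Left, median log2 fold change (knockout minus wild type) of protein-coding genes in 5 equal bins of transcript length and 5 of GC content; right, each library's median log2 deviation from the gene mean in the shortest, longest, lowest-GC and highest-GC bins. Knockout replicates 1 and 2 were higher for short transcripts (0.30 and 0.22), and knockout replicate 3 was lower (-0.11).

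The 12 largest rises included Dpt (log2 2.19), Vtn (vitronectin, 1.74), Clec3b (tetranectin, 1.52), Aspn (asporin, 1.40) and Tnfaip6 (1.34). Ccl11, the chemokine eotaxin, rose by 2.13 (SE 0.466) with a wide spread in the knockout, 19.7 ± 15.4 FPKM. Id3, an inhibitor of basic helix-loop-helix factors, rose by 1.53, Serpina3f by 1.48, Pi16 by 1.43, Lsm5 by 1.36, the chaperone Hsp90aa1 by 1.35 and Sarnp by 1.34. The size of the Lsm5 rise leaned on wild-type replicate 3, at 2.95 FPKM against 12.8 and 9.67 FPKM in wild-type replicates 1 and 2. Serpina3f belongs to a family of near-identical copies and is uncertain for that reason. With the trend removed, Dpt (1.95), Vtn (1.64), Serpina3f (1.34), Pi16 (1.76) and Sarnp (0.87) still passed. The other 7 kept most of their change without passing: Ccl11 (1.65), Id3 (1.32), Clec3b (1.31), Aspn (0.86), Lsm5 (1.11), Hsp90aa1 (1.15) and Tnfaip6 (0.87).

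Besides Pdgfb (log2 -2.25) and Csf2 (-2.18), large falls were those of Kdm6b, a histone H3 lysine 27 demethylase (-1.90), Col1a1, a collagen I chain (-1.88), and the cytoskeletal linker Plec (-1.79). Sema4b (-1.65), Igfbp3 (-1.62), Nos2, inducible nitric oxide synthase (-1.59), Nfatc1 (-1.54), Bcl3 (-1.52) and the basement membrane proteoglycan Hspg2 (-1.51) also fell. Plec went to -0.35 and Hspg2 to -0.16 with the trend removed, while Kdm6b (-1.12) and Col1a1 (-1.19) kept more of their change without passing. Pdgfb (-1.95), Csf2 (-2.59), Sema4b (-1.27) and Igfbp3 (-1.62) still passed in limma after that correction, and Nos2 (-1.27), Nfatc1 (-1.15) and Bcl3 (-1.47) did not.

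**Figure D3:**
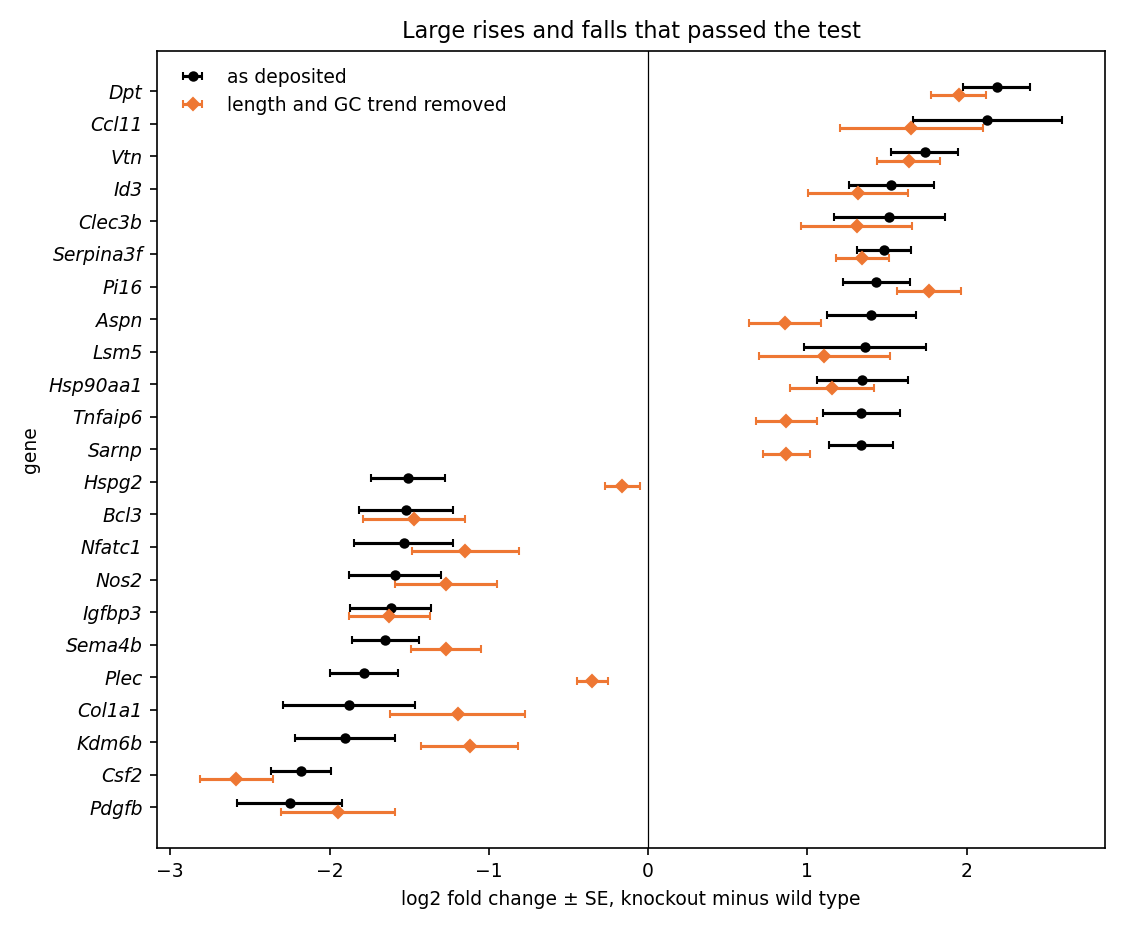
Log2 fold change with its standard error (knockout minus wild type, n = 3 each) of the 12 largest rises and of the large falls reported here, as deposited (black circles) and with the length and GC trend removed (orange diamonds). Csf2 went from -2.18 to -2.59 and Hspg2 from -1.51 to -0.16.

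Of the 12 MHC class II genes tested, 6 rose and 0 fell, and 8 rose and 1 fell when adjusted over the list alone. The class II chains H2-Aa, H2-Ab1 and H2-Eb1, which present peptides to CD4 T cells, rose by 1.11 (SE 0.221), 0.99 (SE 0.228) and 1.24 on the log2 scale. H2-Aa went from 115 ± 29.7 to 245.5 ± 39.0 FPKM. H2-DMa, H2-DMb1 and H2-DMb2, subunits of the peptide exchange factor, rose by 1.03, 0.65 and 0.84. H2-DMb2 was low, at 0.544 ± 0.0918 and 1.78 ± 0.32 FPKM, and passed the filter only through the knockout libraries, so it is uncertain. Cd74, the invariant chain, differed by 0.68 (limma adjusted p = 0.0756) and Ciita, the class II transactivator, by 0.45 (limma adjusted p = 0.126), so neither passed. The list's median was 0.67 (camera adjusted p = 0.00079), but adjusted p = 0.684 with an estimated correlation and 0.0576 with fry. With the trend removed the median was 0.58 (camera adjusted p = 0.00042), and 4 genes passed: H2-Aa, H2-Eb1, H2-DMa and Ciita (1.003, limma adjusted p = 0.0342), while H2-Ab1 (0.79), H2-DMb1 (0.45) and H2-DMb2 (0.64) no longer did.

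Of the 23 MHC class I presentation genes, 6 rose and 1 fell, or 6 and 2 when adjusted over the list alone. The immunoproteasome subunits Psmb8, Psmb9 and Psmb10, which shape the peptides loaded on class I, rose by 0.76, 0.71 and 0.86 on the log2 scale. H2-M3 (0.59), the proteasome activator Psme2 (0.78) and the chaperone Pdia3 (0.61) also rose. Only Psmb9 (0.84) and Psmb10 (0.67) of these passed with the trend removed, where Psmb8 was at 0.64, H2-M3 at 0.35, Psme2 at 0.49 and Pdia3 at 0.49. H2-Q7 fell by 1.17 from a low level, 3.35 ± 0.512 FPKM, and shares sequence with other class I genes, so it is uncertain. Other components did not pass: B2m was at 2275 ± 273 and 3787 ± 1065 FPKM (log2 0.71, limma adjusted p = 0.102), H2-K1 differed by 0.40 (0.234), H2-D1 by 0.16 (0.65, and at -0.15 after quantile normalization), Tap1 by 0.20 (0.382) and the class I transactivator Nlrc5 by -0.07 (0.838). With the trend removed B2m was at 0.235, Tap1 at 0.55 (limma adjusted p = 0.0733) and Nlrc5 at 0.49 (limma adjusted p = 0.0977), again without passing. The list's median was 0.34 (camera adjusted p = 0.00238), with adjusted p = 0.725 with an estimated correlation and 0.187 with fry. Quantile normalization also ended that call, at a median of 0.20 (camera adjusted p = 0.0675), and with the trend removed it was 0.35 (camera adjusted p = 0.000194).

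Interferon gamma response genes were higher as a list, with 9 of 34 rising and 2 falling, or 15 and 2 when adjusted over the list alone. Cxcl9, a chemokine that attracts T cells, rose by 1.25 (24.3 ± 5.07 to 59.0 ± 9.77 FPKM), and the GTPases Gbp3 and Gbp2 by 1.23 and 0.89. Gbp3 missed the threshold after rescaling to TPM (1.14, limma adjusted p = 0.0589) and, with the trend removed, so did Gbp3 (1.06), Gbp2 (0.72), Icam1 (-1.29) and Socs3 (-0.49), leaving 2 members rising and 0 falling. The members that fell were Icam1, an adhesion molecule (-1.39), and Socs3, a cytokine signalling inhibitor (-0.68). Irf1 differed by -0.27 (limma adjusted p = 0.287) and Cd274, the ligand PD-L1, by 0.68 (limma adjusted p = 0.0653). The median was 0.55 (camera adjusted p = 0.00079), with adjusted p = 0.725 with an estimated correlation and 0.257 with fry, and 0.44 (camera adjusted p = 0.00134) with the trend removed. Without wild-type replicate 2 it was 0.34, and 0.19 (camera adjusted p = 0.112) when the trend was removed as well. Without wild-type replicate 1 it was 0.75, so its size depended on which wild-type libraries were kept. The 38 type I interferon stimulated genes had a median of -0.02 (camera adjusted p = 0.942), with Zbp1 rising (1.07) and Trim25 falling (-0.78, or -0.45 without passing once the trend was removed), and 1 and 0 when adjusted over the list alone. Without wild-type replicate 2 their median was -0.26 (camera adjusted p = 0.0203), and -0.35 (camera adjusted p = 0.000397) with the trend removed as well. It was above 0 without wild-type replicate 1 (0.167, camera adjusted p = 0.115), without knockout replicate 3 (0.125) and with array weights (0.202, 0.114), so its direction turned with the library left out.

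NF-kB targets were lower as a list, with 8 of 21 falling and 1 rising, or 9 and 1 when adjusted over the list alone. Besides Csf2 and Bcl3, the cytokines Lif and Csf1 fell by 1.01 and 1.31 on the log2 scale, Csf1 from 135 ± 58.0 to 49.99 ± 1.96 FPKM. Il6 rose (0.93). Members passing with the trend removed were 2 falling, Csf2 among them, and 0 rising, with Lif at -0.74, Csf1 at -0.97 and Il6 at 0.46. The median was -0.58 (camera adjusted p = 0.00079), with adjusted p = 0.695 with an estimated correlation and 0.149 with fry, and -0.47 (camera adjusted p = 0.00134) with the trend removed. It was -0.36 without wild-type replicate 1 and -0.385 without wild-type replicate 3. Of 20 mesenchymal transition genes, 7 fell and 1 rose, the same when adjusted over the list alone, with Tgfb1 at -1.13, the integrin Itga5 at -1.503, fibronectin Fn1 at -1.03 and Snai2 rising by 1.27. Of these only Tgfb1 (-1.11) passed with the trend removed, where Itga5 was at -1.04, Fn1 at -0.40 and Snai2 at 0.88. Their median was -0.30 (camera adjusted p = 0.0127), with adjusted p = 0.684 with an estimated correlation and 0.0576 with fry, and -0.19 without knockout replicate 1. The call ended with the trend removed (-0.19, camera adjusted p = 0.102) but returned when wild-type replicate 2 (camera adjusted p = 0.0337) or knockout replicate 1 (0.0443) was then left out.

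Cytosolic ribosomal protein transcripts were higher as a list, by a median of 0.38 (camera adjusted p = 3.5e-08) over 79 genes, of which Rps27a (1.18) and Rpl17 (0.79) rose singly and 0 did when adjusted over the list alone. The median was 0.14 after quantile normalization, 0.245 without wild-type replicate 1 and 0.248 without knockout replicate 1. The adjusted p was 0.725 with an estimated correlation and 0.323 with fry, and the median was 0.12 (camera adjusted p = 0.00516) with the trend removed. That last call ended without wild-type replicate 1 (0.067, camera adjusted p = 0.151), wild-type replicate 2 (0.093, 0.0835) or knockout replicate 1 (0.057, 0.142), and 0 of its members passed. They took 6.37, 7.09 and 8.19% of fragments in wild type and 10.92, 10.4 and 7.52% in the knockout, with knockout replicate 3 inside the wild-type range. Of 66 ribosome biogenesis genes, 8 rose and 5 fell (12 and 8 when adjusted over the list alone), with Ncl, nucleolin, rising by 1.0 and Tcof1 and Polr1b, factors of ribosomal RNA transcription, falling by 0.79 and 0.69 (median 0.10, camera adjusted p = 0.5). Tcof1 was at -0.27 (limma adjusted p = 0.185) with the trend removed, where 3 of the list rose and 2 fell. Of 35 G2 and mitosis genes, 5 rose and 0 fell (6 and 0 when adjusted over the list alone), with Ndc80 at 1.02 and Bub1 at 0.78, of which only Ndc80 (0.82) passed with the trend removed. Their median was 0.27 (camera adjusted p = 0.000857), with adjusted p = 0.725 with an estimated correlation and 0.187 with fry, and 0.20 (camera adjusted p = 0.00134) with the trend removed. It was 0.16 after rescaling to TPM and 0.17 without wild-type replicate 3, and 0.135 (camera adjusted p = 0.0937) when the trend was removed as well.

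**Figure D4:**
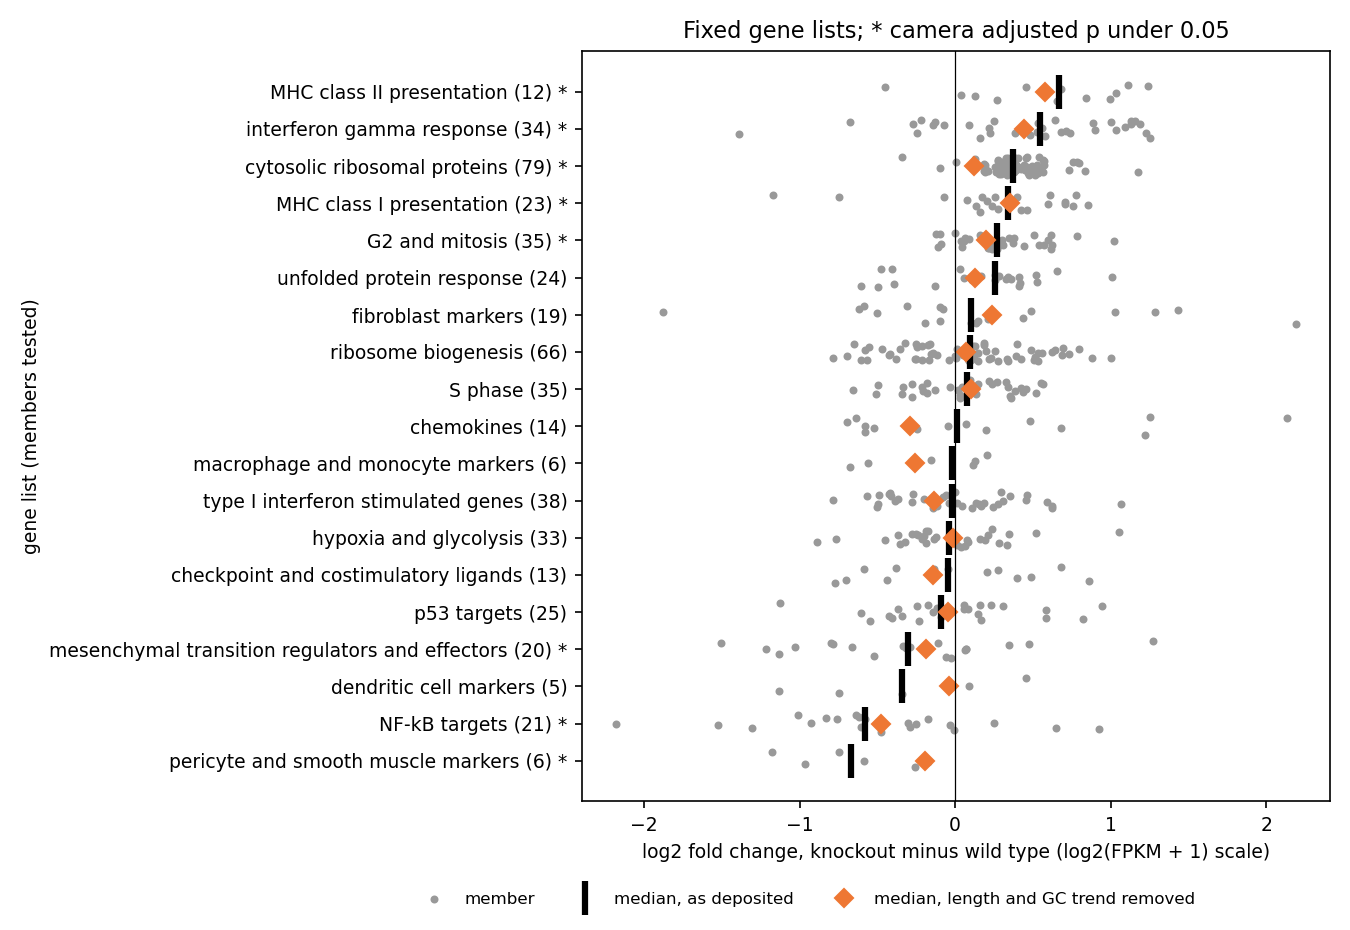
Log2 fold change (knockout minus wild type) of each tested member of the 19 lists with at least 5 tested genes (grey points), with the list median as deposited (black bar) and with the length and GC trend removed (orange diamond). Pericyte and smooth muscle markers went from -0.67 to -0.19, and MHC class II genes from 0.67 to 0.58.

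Fibroblast markers had a median level of 55.3 FPKM (highest 1180 FPKM). The other marker lists had medians below 1 FPKM, with single members such as Krt14 far higher. Ptprc, which encodes CD45, had 0 to 4 fragments per library and was below the filter, as were all T and NK cell markers and all skeletal muscle markers. Of 25 epithelial genes 1, Lgals4, was tested and did not pass (-0.22, limma adjusted p = 0.412). Of 6 pericyte and smooth muscle markers tested, 3 fell and 0 rose (4 fell when adjusted over the list alone): Cspg4 (-1.18), Notch3 (-0.96) and Mcam (-0.75), at -0.29, -0.069 and -0.61 with the trend removed and none of them passing. Their median was -0.67 (camera adjusted p = 0.00178), with adjusted p = 0.684 with an estimated correlation and 0.0576 with fry, and the call ended with the trend removed (-0.19, camera adjusted p = 0.163). With no filter, which admits more members, the median was -0.135 and the list was still called lower (camera adjusted p = 0.00243). Of 19 fibroblast markers, 4 rose (Dpt, Pi16, Dcn and Postn) and Col1a1 fell, or 4 and 2 when adjusted over the list alone. That list's median was 0.10 (camera adjusted p = 0.5), and negative after rescaling to TPM (-0.01), after quantile normalization (-0.10), at a mean of at least 5 FPKM (-0.081), without wild-type replicate 1 (-0.06) and without knockout replicate 2 (-0.027). With the trend removed it was 0.24 (camera adjusted p = 0.00516), with adjusted p = 0.673 with an estimated correlation and 0.0832 without wild-type replicate 1. Haemoglobin transcripts, carried by red blood cells, were higher in the knockout means without passing, with Hba-a1 at 3.77 ± 4.14 and 16.1 ± 11.7 FPKM (limma adjusted p = 0.0709), though 3 of 3 rose when adjusted over the list alone.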

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

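The length and GC correction, limma-voom and their combinations were chosen after seeing the data; the cause was not tested for any change below unless stated. Genes changed (1604) numbered 0 with no filter, 961 after rescaling to TPM, 5454 with array weights, 822 with the replicate block, 290 with the length and GC trend removed, 14 with the replicate block and the trend removed, 231 at 2-fold or more (a stricter criterion) and 2845 at an adjusted p under 0.1 (a looser one). Leaving out each library in turn gave 7 to 2804, and 4 to 535 with the trend removed. Pseudocount 0.1, a mean of at least 5 FPKM, protein-coding genes, median-ratio scaling, quantile normalization, robust or untrended variance and limma-voom gave 1546 to 1972. Deviations of same-numbered samples correlated at -0.185, 0.268 and -0.368, and not every sample correlated best with its own number. These deviations can carry each library's length and GC trend, so the correlations do not decide whether equal numbers mark paired samples.

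The Npm1 difference kept its sign in each alternative and passed with the trend removed (-0.77, limma adjusted p = 0.0423, and 0.0189 to 0.146 when a library was then left out, at -0.89 to -0.68); leaving out libraries with the trend in place gave -0.47 to -0.18 (limma adjusted p 0.228 to 0.508). Lists called (8) numbered 0 with an estimated correlation and 0 with fry, in which no list of the 19 passed. They numbered 8 to 9 with libraries left out, and 5 to 9 when the trend was removed as well. The MHC class I median (0.34) lost its call with quantile normalization (0.20, camera adjusted p = 0.0675), with an estimated correlation (0.34, adjusted p = 0.725) and with fry (0.34, 0.187). The MHC class II median (0.67) lost it with an estimated correlation (0.67, adjusted p = 0.684) and with fry (0.67, 0.0576), and kept it elsewhere (0.37 to 0.84).

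Of 121 other named genes 79 had a call to lose, and 52 lost it with the trend removed, 73 with the replicate block and the trend removed, 79 with no filter, 22 with the replicate block, 16 after rescaling to TPM, 76 without wild-type replicate 3, 61 without knockout replicate 1 and 44 without knockout replicate 2. Signs turned, each for a gene that did not pass, with the trend removed, with or without the block, for Cd14 (-0.048), Cd68 (-0.047), Nlrc5 (0.49), Plin4 (0.28), Pmp22 (-0.061), Prx (0.17) and Xbp1 (-0.027). They also turned with array weights for Pmp22 (-0.017) and Xbp1 (-0.082), after rescaling to TPM for Xbp1 (-0.085), and with quantile normalization for H2-D1 (-0.15) and Xbp1 (-0.027). With libraries left out they turned for Eng (-0.064 to 0.25), Nlrc5 (-0.30 to 0.099) and Xbp1 (-0.052 to 0.102). At 16917778 to 18662688 fragments per library, in simulation, 25.8% of 1.5-fold changes were recovered with 3 libraries each.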

Other observations

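Checkpoint and costimulatory ligands moved both ways, with 2 of 13 rising and 1 falling, or 3 and 4 when adjusted over the list alone (median -0.04, camera adjusted p = 0.942). Raet1d and Raet1e, ligands of the activating receptor NKG2D, rose by 0.86 and 0.49, and Cd276, the ligand B7-H3, fell by 0.59 on the log2 scale. Raet1d and Raet1e are close relatives and may share fragments, and both missed the threshold with the trend removed (0.44 and 0.17), as did Cd276 (-0.27). Of 14 chemokines, 4 rose and 1 fell, the same when adjusted over the list alone, with Ccl8 at 1.22 and Cx3cl1 at -0.69 (median 0.01, camera adjusted p = 0.5). The chemokine median was -0.29 with the trend removed, where Ccl8 was at 0.91 (limma adjusted p = 0.065) and Cx3cl1 at -0.40 (limma adjusted p = 0.154), and 1 member rose and 0 fell. Of 25 p53 targets 2 rose and 2 fell (2 and 3 over the list alone), with the death receptor Tnfrsf10b at -1.12 (camera adjusted p = 0.633). Of 35 S phase genes 3 rose and 2 fell, the same over the list alone, with Pcna at 0.55 and Cdt1 at -0.66 (camera adjusted p = 0.5). Pcna (0.19) and Cdt1 (-0.46) did not pass with the trend removed, nor did any other S phase gene. The S phase list was called higher with the trend removed and without wild-type replicate 2 (0.165, camera adjusted p = 0.0164) or knockout replicate 1 (0.169, 0.0443).

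Of 33 hypoxia and glycolysis genes 0 rose and 2 fell, Car9 (-0.89) and Hk2 (-0.77), with 1 falling over the list alone (camera adjusted p = 0.5), and the list was called lower with array weights (median -0.19, camera adjusted p = 0.0124). Of 24 unfolded protein response genes the chaperone Hsp90b1 rose (1.01) and Sesn2 fell (-0.60), the same counts over the list alone (camera adjusted p = 0.215). Of 5 dendritic cell markers tested 2 fell, Fscn1 (-0.75) and Zbtb46 (-1.13), the same over the list alone (camera adjusted p = 0.245), and of 6 macrophage markers 0 passed, Apoe being at -0.68 (limma adjusted p = 0.0703; camera adjusted p = 0.721). The macrophage list was called lower with the trend removed and without wild-type replicate 2 (-0.50, camera adjusted p = 0.0311). Of the genes named for p53, S phase, hypoxia, unfolded protein response and dendritic lists, Hk2 (-0.37), Sesn2 (-0.23) and Zbtb46 (-0.82) also missed the threshold with the trend removed. With the filter, too few members were tested for a list test among endothelial markers (3), erythroid markers (3), nerve and glial markers (4), adipocyte markers (2), skin keratinocyte markers (2, with Krt14 at 326 ± 57.9 and 390 ± 55.5 FPKM), B and plasma cell markers (1), neutrophil and mast cell markers (1) and pan-leukocyte markers (1). Of the endothelial markers Ramp2 rose by 0.95, or 0.80 without passing once the trend was removed. Plvap was at -0.76 (limma adjusted p = 0.0582), and 1 endothelial marker rose and 1 fell when adjusted over the list alone. With no filter the endothelial list was called lower (median -0.194, camera adjusted p = 0.00478). Gm10241, chosen after its values were seen, had the smallest p of the genes tested and rose from 38.5 ± 3.25 to 279 ± 98.4 FPKM. It is a processed pseudogene of 286 bases, whole within 1 of the 7 Sumo2 transcripts, so it can share fragments with Sumo2 and is uncertain.

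Among the tests below, the gene-count split, both leukocyte tests and the fibroblast share test were chosen only after the result was seen, and the length and GC correction was added after the trend was seen. The number of genes changed may rest in part on the length and GC trend. With it removed, 12.7% of the called genes kept their call, between the bounds of 10% and 50% set for the test, so the trend as the whole cause cannot be told apart from other causes by it. The median size of the called genes' changes went from 0.72 to 0.38 while the median standard error went from 0.17 to 0.12, and 97.2% kept their sign. A smaller standard error does not by itself end a call, and the changes shrank by the larger share. These medians do not decide why single calls ended, since an adjusted p also depends on the p-values of the other genes. Unadjusted limma p was under 0.05 for 3740 genes as deposited and for 2911 with the trend removed. Ccne1 lost its call though its change went from -0.51 to -0.60 (limma adjusted p = 0.0383 and 0.0575). Whether the trend is itself technical stays open, since it differs between replicates of 1 group as well as between groups. The real split gave 1604 genes and the highest of the other 9 gave 1, but 10 splits are too few for a share under 0.05, the real split being the only 1 to reach that number.

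The higher MHC lists were set against the trend, leukocytes left after CD45 depletion, and the grouping. Host cells other than leukocytes, such as fibroblasts, were not tested as a source of the higher lists. The trend as the whole cause is argued against, since the medians were 0.35 (class I) and 0.58 (class II) without it. This holds as far as the longest annotated transcript stands for each gene's length and GC content. Only 14 of 103 leukocyte markers were tested, with a median of 0.058 (median absolute deviation 0.405, 0 of 14 rising). That lies below the class II median by more than the spread, as the criterion asked, but leaves class I undecided. The 14 include Bst2 (273 FPKM in wild type) and Fscn1 (199 FPKM) while Ptprc was below the filter, so other cells may express them. Their fold changes therefore do not decide on leukocytes for either list. A level test, added once that outcome was known, argues against leukocytes for both lists: the 10 pan-leukocyte markers had a median of 0.0474 FPKM in the knockout, with only Arhgdib, which the tumour cells may express, above 1. Its bound, at most 1 of the 10 markers at a mean of 1 FPKM, was set with the levels partly known. For the split test 10 splits are too few. Counting the real split itself, 3 of them gave a class I camera p as small as the real 0.000876 (smallest other 2.35e-07), 1 a class II p as small as 0.000166 (smallest other 0.000345), and 3 as many lists as the real 8 (highest other 11). Each of the other splits called at least 2 lists. Camera at its preset correlation thus also called lists between groups that mixed the labels.

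The fibroblast markers that changed may reflect a different share of host fibroblasts, which the MC38 tumours would carry past a CD45 depletion. Of the 5 that passed, 4 rose and 1 fell (Col1a1), and a share change would move them one way, but 1 gene does not decide. That test first counted any fall as excluding a share change, and it was made stricter after Col1a1 was seen to be the only one. With the trend removed 2 of the 5, Dpt (1.95) and Pi16 (1.76), kept their call, so length and GC bias cannot be told apart for the set by the count. Dcn went from 1.28 to 0.94, Postn from 1.03 to 0.69 and Col1a1 from -1.88 to -1.19, so most of each change remained. A difference in the tumour cells themselves, which the genotype names, was not tested separately.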
